A study of Mus musculus with 5 samples.

How the data were processed

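RNA sequencing was analysed for 5 libraries made from cells sorted by flow cytometry from whole mouse brain. The labels describe C57BL/6J hosts that received whole-body irradiation of 1000 rad and, at 8 weeks of age, bone marrow from UBC-GFP donors, which carry a green fluorescent protein transgene driven by the ubiquitin C promoter. Brains were taken 8 months after the transplant, and the labels give an age of 9 months. The labels put 2 libraries in the group of endogenous microglia and 3 in the group of engrafted macrophages. The antibodies and gates of the sort are not given in the sources used here. Per the labels' protocols, RNA was isolated on RNeasy columns and amplified with the Ovation RNA-Seq V2 kit before the cDNA was fragmented. Nothing in the labels says that the replicates came from separate animals, so all p-values measure only the spread between these samples, which may be technical.

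The authors deposited a table of raw counts per Ensembl gene, with 1 column per library and no normalization. Per the submitters' processing notes, FastQC, STAR and HTSeq were used and the genome build was mm9. Versions, annotation release, strand setting and read filters are not given in the sources used here. The table has 47729 gene rows, and no row was a summary of unassigned reads. Symbols came from the GENCODE vM21 annotation, which matched 47224 of the identifiers. The other 505 identifiers were kept in library sizes and tests and took 0.119% to 0.161% of the counts of a library. Because that annotation is on another genome build than the one named, no coordinates are given, and it was used only for names and for which genes overlap each other. Of 160 named genes, 39 had exons overlapping those of another gene in that annotation, and for 7 (*Adora3*, *Cnp*, *Kcnj13*, *Ltbp3*, *Npc1*, *Pltp* and *Rac1*) the other gene held at least 10% as many counts, so their values are uncertain without a known strand setting. Genes with near-identical copies can share reads, and their values are uncertain for the same reason. These include the *Ifitm*, *Oas1*, *Ifi200*, *Ly6c*, *C4*, *Ms4a*, H2 and protocadherin families.

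Total counts per library ran from 17380388 to 29237644, so 1 count was worth 0.0342 to 0.0575 CPM before the scaling of libraries described below. A group with no count for a gene was given a floor of 3 counts over the whole group. After that scaling the floor is 0.0510 CPM in microglia and 0.0434 CPM in macrophages, and a fold against it is a lower bound. For genes with 1 to 3 counts in a group, the ratio is given with an exact conditional (binomial) 95% interval. Intervals and floors cover counting error only, because reads from amplified cDNA without molecular identifiers are not independent molecules. No pair of libraries was a duplicate. Within groups, the chi-square per degree of freedom between the counts of a pair of libraries was 28.3 to 42.1, and between groups it was 213 to 299.

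Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, glmQLFit and glmQLFTest) in a model with the group as its only term, fitted to all 5 libraries with 3 residual degrees of freedom. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by the trimmed mean of M values (TMM), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are macrophages over microglia. Standard errors (SE) of log2 fold changes are approximate, taken as the absolute log2 fold change over the square root of F. Values per library are TMM-scaled CPM. Principal components and correlations used log2 CPM with a prior count of 2.

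A set of 30 gene lists, holding 776 symbols of which 772 matched, was fixed before the data were examined, as were the test, the named genes and the alternatives, unless stated otherwise. Lists were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Camera with the correlation estimated from the data and fry were run beside it. The lists of homeostatic microglia and of bone marrow-derived brain macrophages hold genes named in earlier engraftment studies, possibly on these samples. Named genes were chosen by a rule in 3 parts. The first part took, among genes past the threshold, the 12 with the largest positive and the 12 with the largest negative log2 fold change, given a mean of at least 20 CPM in the higher group, group ranges that did not overlap, and a symbol that is not a predicted model. The second took, in each list, up to 4 genes past the threshold with the largest absolute log2 fold change and at least 10 CPM in the higher group, and up to 2 genes of the highest mean CPM that did not pass. The third took 18 fixed genes (*Ptprc*, *Itgam*, *Csf1r*, *Cx3cr1*, *Aif1*, *Tmem119*, *P2ry12*, *Sall1*, *Ms4a7*, *Clec12a*, *Apoe*, *Cd74*, *H2-Aa*, *Ccr2*, *Ly6c2*, *Spi1*, *Irf8* and *Runx3*). Genes outside the rule are marked as chosen after their values were seen.

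The tests were first run on simulated data for macrophages against microglia, drawn from the means and library sizes of these libraries, in 10 runs with 200 changed genes each and a median of 15503.5 genes tested. edgeR recovered 26.2% of genes changed 2-fold and 58.2% of those changed 4-fold, none with the wrong sign, and 8.77% of its calls were false. DESeq2 recovered 34.6% and 66.7%, with 29.8% of its calls false. limma-voom recovered 25.6% and 54.9%, with 9.90% false. The adjusted threshold depends on how many genes change, and 2779 genes were called in the real data, so these rates need not hold there. Camera called a list raised by 0.8 on the log2 scale in 20 of 20 runs on 16172 genes and made 1 false call in 480 tests of unchanged lists. Simulated genes were drawn independently of each other, so these runs cannot show how often camera makes false calls where genes are correlated.

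The alternatives set before the data were examined were DESeq2 size factors, total count and upper quartile scaling, no filter on low counts and a stricter one (at least 5 CPM in at least 2 libraries), DESeq2 1.42.0, limma-voom, a robust fit, a test against a 2-fold change, the replicate number as a block, and leaving out each library. Leaving out mitochondrially encoded genes, and leaving out of every list the genes found in more than 1 list, were chosen after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Permuting the group labels was left out because microglia have 2 libraries.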

Results

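Gene expression was measured by RNA sequencing in bone marrow-derived macrophages that had settled in the brain and in the microglia of the same kind of host, 8 months after irradiation and transplantation of marrow carrying green fluorescent protein. Microglia are the resident macrophages of the brain parenchyma. The design asks whether marrow-derived cells that engraft the brain take on the expression profile of microglia or keep a different one. There were 2 libraries of microglia, with 26012422 and 29237644 counts, and 3 of engrafted macrophages, with 29225813, 25615550 and 17380388 counts for replicates 1, 2 and 3. At least 1 count was found for 18795 to 19892 genes per library. Mitochondrially encoded genes took 13.3% ± 1.01 of the counts in microglia (SD, n = 2) and 19.4% ± 0.885 in macrophages (n = 3), most of it the mitochondrial ribosomal RNAs, with 11.8% ± 0.908 and 17.6% ± 0.931. All levels are CPM given as mean ± SD over the 2 microglia and 3 macrophage libraries.

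The libraries separated by cell group. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.924 between the microglia libraries, 0.934 to 0.948 between the macrophage libraries and 0.836 to 0.868 between groups. The first principal component held 59.4% of the variance, with microglia at -125 and -99.7 and macrophages between 66.1 and 82.4. The second held 17.2% and spread the microglia libraries apart (72.7 and -83.2), and the third held 13.97% and spread macrophage replicates 1 and 2 (-74.5 and 66.2).

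Engrafted macrophages differed from microglia across a large part of the transcriptome. Among genes shared by the macrophage lineage some did not pass the threshold and *Itgam* was lower in macrophages. The colony-stimulating factor 1 receptor gene *Csf1r* stood at 3374 ± 254 in microglia and 3114 ± 207 in macrophages, the lineage-determining factor *Spi1* at 169.9 ± 3.01 and 167.9 ± 45.3, and *Irf8* at 295.9 ± 19.8 and 250.6 ± 24.4, none past the threshold (edgeR, adjusted p = 0.536, 0.972 and 0.275). *Ptprc*, which encodes CD45, stood at 662.6 ± 122 and 917.8 ± 113 (adjusted p = 0.0565). It passed without microglia replicate 1 (adjusted p = 0.0277) or macrophage replicate 1 (0.0452), with DESeq2 (0.0163), limma-voom (0.0229), a stricter filter (0.0322) or no filter (0.00717), so its call depends on the test. *Aif1*, which encodes IBA1, stood at 227.4 ± 3.67 and 285.7 ± 74.6 (adjusted p = 0.330) and passed without macrophage replicate 2 (0.0215). *Itgam*, which encodes CD11b, was lower in macrophages (2370.0 ± 152 against 1066 ± 207, log2 fold change -1.15, SE 0.154, adjusted p = 0.000470).

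Of 16172 genes tested, 2779 (17.2%) passed the threshold, 1604 higher and 1175 lower in macrophages. More than 4-fold differences were found for 846 of the higher and 375 of the lower genes. The 2 groups' ranges were apart for all 2779 called genes and for 45.7% of all tested genes, where chance gives 20%. At an unadjusted p under 0.05 there were 4682 genes. Scaling to the total count alone shifted the median log2 fold change of all genes from 0.0070 to -0.141 and the higher share of the calls from 57.7% to 45.2%, and 1014 genes passed a test against a 2-fold change. Without macrophage replicate 2, the library with the most neutrophil transcripts, 2220 genes passed, 1301 higher and 919 lower.

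The largest differences in favour of macrophages included genes with no count in microglia. *Ttr* (ENSMUSG00000061808), the transthyretin gene abundant in choroid plexus, was at least 1491-fold higher in macrophages. The neutrophil granule genes *Ltf* and *Mmp8* were at least 1063-fold and 851-fold higher, the neutrophil surface gene *Cd177* at least 441-fold, the leukocyte homing receptor gene *Sell* at least 776-fold and the Schlafen family gene *Slfn4* at least 429.6-fold. The histidine decarboxylase gene *Hdc*, with 2 counts in microglia, had a ratio of 1552 (95% counting interval 429 to 12818), and *Emb*, with 3, a ratio of 536 (183 to 2600). Also among the 12 were *Lcn2* and *S100a8*, both neutrophil genes, *Ifitm6*, and *Runx3* (ENSMUSG00000070691), a transcription factor gene of blood cell lineages, which rose from 0.278 ± 0.184 to 137.8 ± 30.7 (log2 fold change 8.88, SE 0.388, edgeR adjusted p = 2.454e-07). Neutrophil markers summed to 444 and 480 CPM in the microglia libraries and to 920.1, 1833 and 895 in macrophage replicates 1, 2 and 3. Most of the microglia sum was *Csf3r*, chosen after its values were seen (456.8 ± 29.9 in microglia), and *S100a8* stood at 0.333 ± 0.159 there. Of the 12 higher genes, *Ltf*, *Mmp8*, *Sell*, *Cd177*, *Slfn4*, *Hdc*, *Lcn2*, *S100a8* and *Ifitm6* were highest in macrophage replicate 2, as was the neutrophil marker sum. *Slfn4* stood at 12.2, 39.0 and 14.6 CPM in macrophage replicates 1, 2 and 3, and *Hdc* at 40.7, 77.2 and 35.9. *Ttr* and *Runx3* were highest in replicate 1 and *Emb* in replicate 3. Which cells held these transcripts was not tested. With limma-voom *Ttr* and *Sell* did not pass (adjusted p = 0.101 and 0.0583). The 12 genes with the largest difference in favour of microglia were *Col6a3*, *Adamts16*, *Plekhh2*, *Myo18b*, *Ache*, *Csmd3*, *Sall3*, *Nav3*, *Tmem44*, *Cacna1a*, *Sall1* and *Slc1a3*. *Nav3* stood at 556.6 ± 56.4 in microglia and 24.2 ± 3.06 in macrophages (log2 fold change -4.53, SE 0.155, adjusted p = 8.894e-08). The glutamate transporter gene *Slc1a3*, best known from astrocytes, stood at 126.7 ± 14.4 and 6.30 ± 1.81.

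Genes of microglial identity were lower in engrafted macrophages, but to very different extents. Of 34 homeostatic microglia genes tested, 29 were lower, 0 higher and 5 past no threshold (30 lower when adjusted over the list alone), with a median log2 fold change of -1.11. *Sall1* (ENSMUSG00000031665), a transcription factor gene that in the brain marks microglia, stood at 685 ± 24.3 in microglia and 33.1 ± 6.36 in macrophages (log2 fold change -4.37, SE 0.168, edgeR adjusted p = 1.078e-07), and *Sall3* at 141.9 ± 0.892 and 6.13 ± 0.235. The fructose transporter gene *Slc2a5* (log2 fold change -3.96, SE 0.204) and *Upk1b* (-4.29, SE 0.340) were also far lower. The purinergic receptor gene *P2ry12* fell from 2145 ± 276 to 515.5 ± 69.7, *Tmem119* from 859.3 ± 31.0 to 327 ± 71.7 and the fractalkine receptor gene *Cx3cr1* from 2464 ± 123 to 1359 ± 189 (log2 fold changes -2.06, -1.39 and -0.86). *Fcrls*, by contrast, stood at 1087 ± 21.8 and 1044 ± 203 (log2 fold change -0.06, SE 0.155, adjusted p = 0.860). The list was lower than other genes by camera (adjusted p = 1.089e-41), but its adjusted p was 0.0630 with an estimated correlation. Many of its genes were chosen in studies of microglia and engrafted cells, possibly on these samples, so its direction is not independent evidence.

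**Figure D1:**
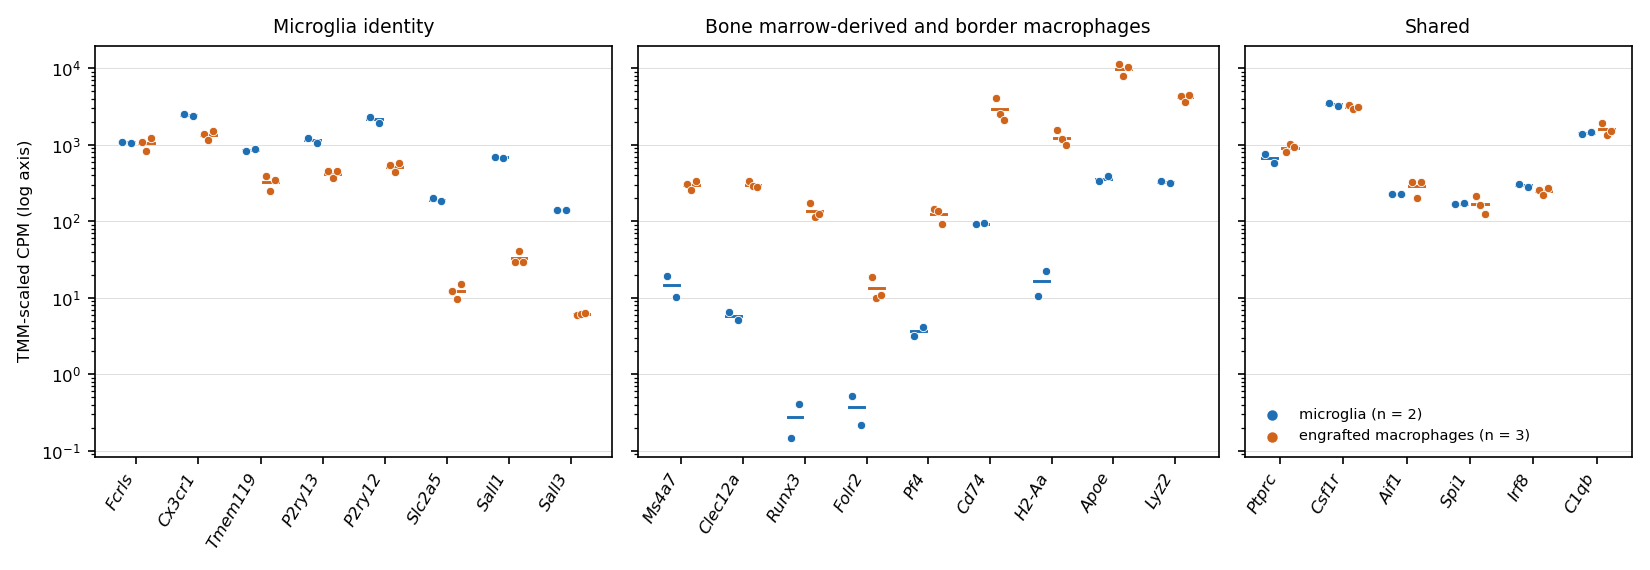
TMM-scaled CPM of genes of microglial identity, of marrow-derived and border macrophages, and shared by both groups, on a log axis. Each point is a library (microglia n = 2, engrafted macrophages n = 3) and each bar a group mean. *Sall1* and *Sall3* were more than 4-fold apart between groups, while *Fcrls* and *Csf1r* overlapped or lay close.

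Genes reported in marrow-derived brain macrophages were higher in 26 of 28 cases, lower in 0, with a median log2 fold change of 4.17 (26 over the list alone, which is not independent evidence, since such studies may include these samples). Camera gave an adjusted p of 1.394e-110, and 0.00669 with an estimated correlation. *Apoe* (ENSMUSG00000002985), which encodes the lipid carrier apolipoprotein E, rose from 363 ± 43.8 to 9872 ± 1701 (log2 fold change 4.77, SE 0.181, edgeR adjusted p = 1.078e-07). *Ms4a7* rose from 14.8 ± 6.52 to 299.7 ± 38.0 and the lectin receptor gene *Clec12a* from 5.82 ± 0.897 to 301.7 ± 31.5 (log2 fold changes 4.34 and 5.70, SE 0.280 and 0.198). *Ms4a6d* and *Ccl12* did not pass, with log2 fold changes of 0.33 and 0.17.

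Markers of the macrophages at the brain's borders were higher for 19 of 22 genes (20 over the list alone), with 0 lower and a median log2 fold change of 4.04. The list's adjusted p was 7.125e-50 by camera and 0.0459 with an estimated correlation. The chemokine gene *Pf4* rose from 3.67 ± 0.678 to 124.1 ± 27.1 and the folate receptor gene *Folr2* from 0.370 ± 0.212 to 13.3 ± 4.98 (log2 fold changes 5.07 and 5.17). *Maf* was at 394.6 ± 38.4 and 515.6 ± 41.7 (adjusted p = 0.0643), and passed with a stricter filter (0.0413), DESeq2 (0.0207) and limma-voom (0.0359). Of 25 monocyte genes 24 were higher and 0 lower (24 over the list alone), with a median log2 fold change of 5.74 that stayed the same with its 6 genes absent from microglia at their bound. Camera gave 8.872e-29, and 0.0446 with an estimated correlation. *Ccr2*, the receptor used by monocytes to leave the marrow, rose from 8.14 ± 2.22 to 81.2 ± 26.0, and *Ly6c2* stood at 0.111 ± 0.157 and 9.66 ± 6.34 (log2 fold changes 3.32 and 6.45, SE 0.315 and 1.07). limma-voom did not call *Ly6c2* (adjusted p = 0.0544). *Ccr2*, *Ly6c2*, *Sell*, *Hp* and *Chil3* of this list were highest in macrophage replicate 2, together with the neutrophil markers. Without macrophage replicate 2, 22 monocyte and 19 border macrophage genes were higher. Since the gates of the sort are not given, monocytes or border macrophages could have been among the sorted cells. Which cells held the transcripts of these 2 lists was not tested.

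Antigen presentation genes were higher in part. Of 16 class II genes, 9 were higher and 0 lower (10 over the list alone), with a median log2 fold change of 1.14. *Cd74*, the invariant chain gene, rose from 92.7 ± 2.15 to 2934 ± 1062, and *H2-Aa*, which encodes a class II alpha chain, from 16.5 ± 8.51 to 1244 ± 282 (log2 fold changes 4.98 and 6.23, SE 0.287 and 0.362). *H2-Ab1* and *H2-Eb1* had log2 fold changes of 5.91 and 5.90, while the protease gene *Ctss* stood at 3231 ± 37.1 and 3311 ± 792. The class II list had an adjusted p of 3.562e-15 by camera and of 0.0699 with an estimated correlation. Dendritic cell markers were higher in 8 of 16 cases in the same libraries, and the gates of the sort are not given. Which cells held the class II transcripts was not tested. Of 22 class I genes, 5 were higher (8 over the list alone) and 0 lower, and the list did not pass (camera adjusted p = 0.134). The 5 fell to 2 without macrophage replicate 1 and to 2 without macrophage replicate 3, were 3 with 2 lower under total count scaling, and rose to 8 with DESeq2 and 10 with no filter. They were *Nlrc5*, a regulator of class I genes (log2 fold change 1.98), *H2-T23* (0.85), *Psmb8* (0.79), *Psme1* (0.71) and *B2m* (0.51), the last chosen after its values were seen. *Psmb8* did not pass without microglia replicate 2 or macrophage replicate 1 or 3 (adjusted p = 0.121, 0.0840 and 0.0929), nor *Psme1* without microglia replicate 1 or macrophage replicate 1 or 3 (0.123, 0.0809 and 0.0686) or with total count scaling (0.0518). *H2-K1* and *H2-D1* had log2 fold changes of -0.09 and 0.38 (adjusted p = 0.747 and 0.150), and *H2-D1* passed without microglia replicate 2 (0.0164) and with no filter (0.0437).

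Type I interferon response genes were higher in 29 of 39 cases and lower in 0 (33 over the list alone), with a median log2 fold change of 1.69. The antiviral gene *Oas3* rose from 0.794 ± 0.966 to 27.3 ± 5.12 and *Ifitm3* from 12.6 ± 2.93 to 178 ± 34.8 (log2 fold changes 5.06 and 3.82, SE 0.717 and 0.243). The interferon-inducible chemokine gene *Cxcl10* stood at 353.8 ± 2.35 and 288 ± 32.1 (adjusted p = 0.165), and was called lower with total count scaling (0.0286), the 1 lower gene of the list there. Camera gave an adjusted p of 2.743e-16 for the list, and 0.0470 with an estimated correlation.

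Genes of the disease-associated microglia programme were split. Of 28, 15 were higher and 4 lower (18 and 5 over the list alone), with a median log2 fold change of 0.91. *Apoe*, *Igf1* (log2 fold change 4.28) and the lysozyme gene *Lyz2* (3.66) were higher. The lower genes were *Csf1*, which encodes the ligand of the *Csf1r* product, from 515.7 ± 37.3 to 32.0 ± 0.918 (log2 fold change -4.01, SE 0.132), *Ctsl* (-1.28), and *Cst7* (-1.84) and *Cd9* (-1.85), the last 2 chosen after their values were seen. *Tyrobp* and *Ctsd* had log2 fold changes of 0.36 and 0.43 (adjusted p = 0.109 and 0.183), and passed without macrophage replicate 2 (0.0291 and 0.00189), and *Ctsd* with no filter (0.00565). Camera gave an adjusted p of 1.303e-07, and 0.310 with an estimated correlation.

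Among complement components and Fc receptors, 6 of 21 were higher and 4 lower (7 and 5 over the list alone, camera adjusted p = 0.556). *C3* rose from 23.9 ± 18.7 to 126.1 ± 15.03, with *C4b* and *Cfp* at log2 fold changes of 2.75 and 2.98. *C1qb* stood at 1420.1 ± 50.9 and 1599 ± 302 (adjusted p = 0.512). The lower genes were *Itgam*, and *C5ar1*, *Cfh* and *Itgb2* (log2 fold changes -0.97, -1.31 and -0.55), these 3 chosen after their values were seen. Engulfment genes moved both ways, with 7 of 26 higher and 9 lower (7 and 10 over the list alone). The scavenger receptor genes *Msr1* and *Cd36* and the receptor tyrosine kinase gene *Axl* were higher (log2 fold changes 4.70, 4.37 and 3.41, SE 0.196, 0.206 and 0.156), and the integrin gene *Itgb3* was lower (-3.23, SE 0.284). The engulfment list's median was -0.19, its mean 0.36, and its camera direction up (adjusted p = 0.556). Without the genes it shares with other lists it was called lower (adjusted p = 0.0436). In the lipid and cholesterol list 10 of 33 were higher and 4 lower (13 and 4 over the list alone), with a camera adjusted p of 3.393e-06, of 0.0699 with an estimated correlation, and of 0.247 without genes shared with other lists. Its lower genes, chosen after their values were seen, were *Abca9*, *Lrp1*, *Mylip* and *Scd2*, and 2 were called without microglia replicate 1. Of 43 lysosome genes 9 were higher and 4 lower (13 and 6 over the list alone, camera adjusted p = 0.252, and 0.0358 without macrophage replicate 2). *Ctsc* rose from 310.0 ± 2.47 to 1480.2 ± 75.4, and 8 were lower with total count scaling. *Ctsl*, *Ctsf* and, chosen after their values were seen, *Hexb* and *Cst3* were lower.

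Signalling genes also moved in both directions. Of 36 cytokine and chemokine genes, 14 were higher and 9 lower (15 and 9 over the list alone). *Vegfa* rose from 5.73 ± 5.32 to 229.8 ± 36.7 and the anti-inflammatory cytokine gene *Il10* from 2.39 ± 0.178 to 59.9 ± 8.70. *Tnf* and *Il1a*, inflammatory cytokine genes chosen after their values were seen, had log2 fold changes of -2.47 and -2.03 (SE 0.126 and 0.128). Camera did not call the list (adjusted p = 0.130), but did so without microglia replicate 1 (0.0133) or 2 (0.00779). Among macrophage transcription factors, 11 of 42 were higher and 7 lower (12 and 9 over the list alone, camera adjusted p = 0.505). *Ahr*, which encodes the aryl hydrocarbon receptor, rose from 1.96 ± 0.903 to 175.8 ± 4.92 (log2 fold change 6.50, SE 0.290, edgeR adjusted p = 2.711e-07), while *Zeb2* and *Mef2a* stood at log2 fold changes of 0.02 and -0.28 (adjusted p = 0.922 and 0.116). *Mef2a* was called lower with total count scaling (0.0140) and limma-voom (0.0438), and total count scaling gave 12 lower genes in the list. This list's median was -0.02 and its mean 0.60. Adhesion and migration genes were higher in 18 of 37 cases and lower in 11 (19 and 13 over the list alone). *Cxcr4*, the receptor that holds blood-forming cells in the marrow, rose from 4.83 ± 0.806 to 337.2 ± 47.1 and the integrin gene *Itgal* from 1.59 ± 1.32 to 83.7 ± 5.78. Camera gave an adjusted p of 0.000224 for this list, and 0.113 with an estimated correlation. Its members *Sell* and *Mmp9* were highest in macrophage replicate 2, together with the neutrophil markers.

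TGF-beta signalling genes were lower in 10 of 27 cases and higher in 4 (the same numbers over the list alone). The receptor genes *Bmpr1a* and *Eng* fell (log2 fold changes -3.56 and -2.32, SE 0.369 and 0.218), and *Tgfb3* rose from 0.471 ± 0.667 to 29.7 ± 1.65. The other higher genes were *Ltbp3* and, chosen after their values were seen, *Itgb8* and *Nrros*. *Ltbp3* did not pass without microglia replicate 1 (adjusted p = 0.155) or macrophage replicate 2 or 3 (0.101 and 0.182), with total count scaling (0.0559) or with limma-voom (0.0626), and 2 genes of the list were higher without microglia replicate 1, without macrophage replicate 2 or with total count scaling. Camera gave 0.0960 for the list, 0.0430 without macrophage replicate 1 and 0.0402 with total count scaling. The median of its log2 fold changes was -0.17 and the mean 0.25. Of 24 purinergic and neurotransmitter receptor genes 5 were higher and 5 lower (7 and 7 over the list alone, camera adjusted p = 0.371, median 0.24, direction down). The lower ones were *P2ry12*, *P2ry13*, *Adora3*, *Gabbr1* and *Entpd1*. The higher ones were *P2ry14*, *P2rx4*, *Adora2a*, *Adora2b* and *Gria4*, which, like *Entpd1*, were chosen after their values were seen, and the number higher was 2 without microglia replicate 1, 3 without macrophage replicate 1 and 2 without macrophage replicate 3, with a stricter filter or by limma-voom.

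The transcription factor p53 answers DNA damage. Many genes of the p53 and DNA damage response list were lower in macrophages than in microglia. Of 31 genes, 15 were lower and 4 higher (15 and 4 over the list alone), with a median log2 fold change of -0.91. Without microglia replicate 2, 9 were lower and 2 higher, and without macrophage replicate 3, 2 were higher. *Cdkn1a* (ENSMUSG00000023067), which encodes the cell cycle inhibitor p21, stood at 1269.8 ± 172 in microglia and 344 ± 116 in macrophages (log2 fold change -1.88, SE 0.224, edgeR adjusted p = 0.000219). *Gdf15* stood at 21.0 ± 8.05 and 2.71 ± 0.698 and the nuclease gene *Aen* at 14.3 ± 5.04 and 3.70 ± 0.212 (log2 fold changes -2.95 and -1.95). *Aen* did not pass without microglia replicate 2 (adjusted p = 0.0563). *Mdm2*, which encodes the ligase that degrades p53, and *Ccng1*, both chosen after their values were seen, had log2 fold changes of -0.73 and -1.02. The 4 higher genes were *Pltp* and, chosen after their values were seen, *Sesn1*, *Pmaip1* and *Plk2*. *Btg2* stood at 935.4 ± 41.2 and 861.1 ± 69.6. Camera gave an adjusted p of 0.00331 for the list, and 0.117 with an estimated correlation. All libraries came from irradiated hosts.

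Of 34 cell cycle genes, 6 were higher and 0 lower (6 over the list alone), with 3 higher without macrophage replicate 3 and 10 by DESeq2. *Mki67*, a marker of dividing cells, rose from 15.6 ± 4.51 to 55.6 ± 2.47 and the topoisomerase gene *Top2a* from 7.60 ± 0.000972 to 25.2 ± 8.50 (log2 fold changes 1.83 and 1.73, SE 0.239 and 0.335). *Pcna* stood at 89.6 ± 3.81 and 77.0 ± 10.3. The list passed narrowly by camera (adjusted p = 0.0494) and did not pass with an estimated correlation (adjusted p = 0.531), without microglia replicate 1 (0.111) or without macrophage replicate 2 (0.111) or 3 (0.0701). Immediate early and dissociation stress genes were higher in 9 of 30 cases and lower in 7 (10 and 9 over the list alone, camera adjusted p = 0.895), with a median of 0.01. *Fosb* and *Klf4* rose by log2 fold changes of 1.27 and 1.66 (SE 0.136 and 0.146), and *Egr1* and *Egr3* had log2 fold changes of -1.95 and -2.69 (SE 0.127 and 0.222).

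**Figure D2:**
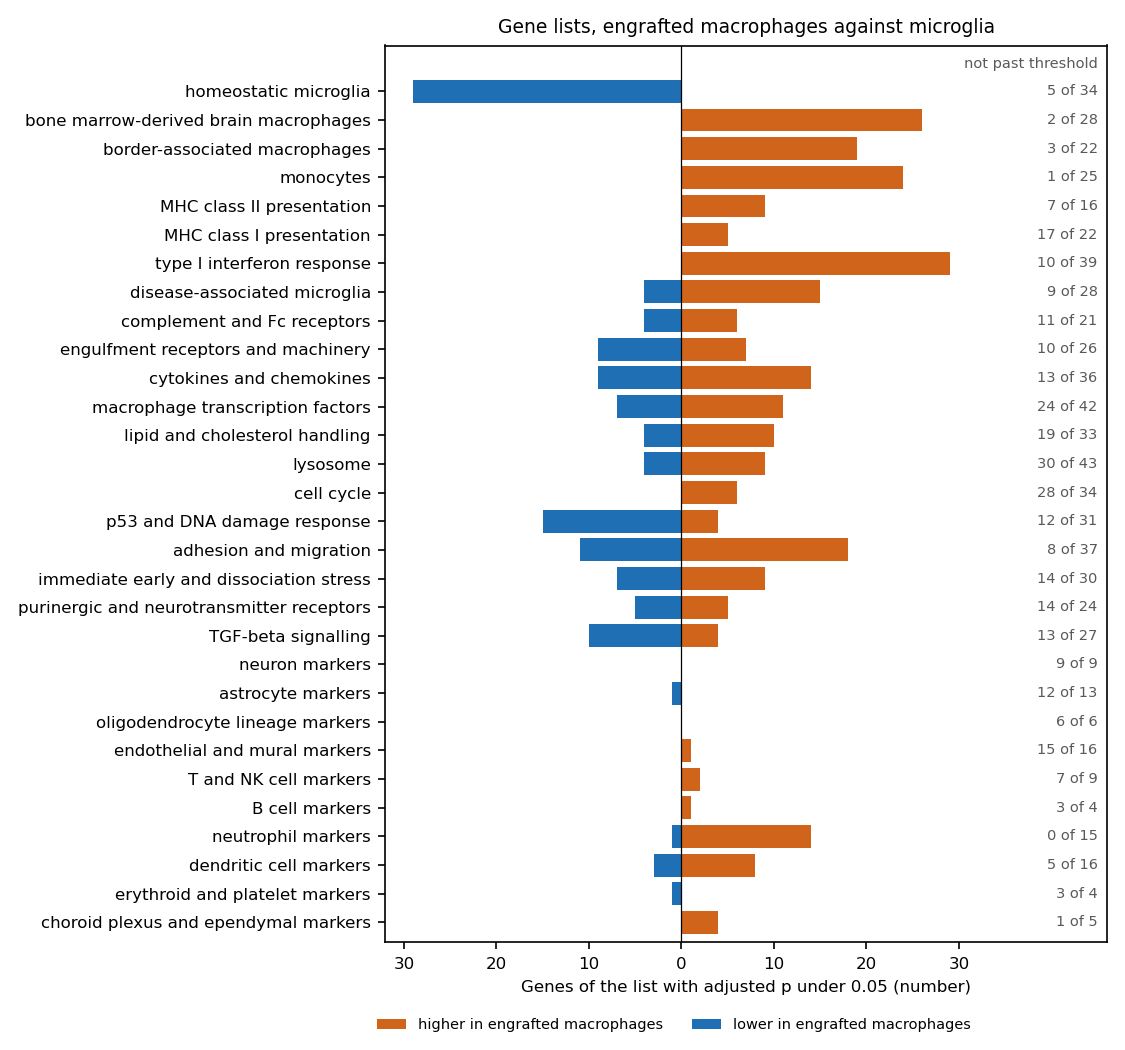
Number of genes of each of the 30 lists that were higher (right of 0) or lower (left of 0) in engrafted macrophages than in microglia at the threshold, with the number that did not pass out of those tested at the right edge. The homeostatic microglia list has 29 lower and 0 higher genes and the type I interferon list 29 higher and 0 lower genes.

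Markers of other cell types were checked for cells that the sort could have carried along, and those of monocytes and border macrophages are given above. No neuron marker (9 tested) or oligodendrocyte lineage marker (6 tested) passed in the edgeR test of all libraries (camera adjusted p = 0.812 and 0.9998), with 1 higher and 1 lower in each list at an unadjusted p under 0.05 and 0 by limma-voom. DESeq2 called *Syn1* and *Mbp* higher and *Plp1* lower, edgeR called *Mbp* with a stricter filter (adjusted p = 0.0486) and *Syn1* with no filter, and 2 neuron markers were higher without microglia replicate 2 (*Syn1* and *Plp1* were chosen after their values were seen). *Snap25* stood at 9.07 ± 4.69 and 9.23 ± 1.97. Of 13 astrocyte markers *Slc1a3* passed, lower in macrophages (camera adjusted p = 0.258), with 2 lower without microglia replicate 2, 2 by DESeq2 and 3 with total count scaling, among them *Slc1a2* (adjusted p = 0.0414). Of 16 endothelial and mural markers *Flt1* was higher (log2 fold change 1.99, camera 0.681 for the list), and it did not pass without macrophage replicate 1, 2 or 3 (adjusted p = 0.0640, 0.0620 and 0.0745), while 1 marker was lower without macrophage replicate 3 and 1 with no filter. Of 9 T and NK cell markers *Gzma* and *Gzmb*, chosen after their values were seen, were higher at 2.06 and 2.68 CPM in macrophages with no count in microglia (camera 0.263 for the list), with 1 higher by limma-voom, 5 with no filter and 0 of 3 tested with a stricter one, and 1 marker was lower without microglia replicate 2. Of 4 B cell markers *Cd22* was higher (camera 0.590), and of 4 erythroid and platelet markers *Gp9*, chosen after its values were seen, was lower (camera 0.782), which was not called without microglia replicate 2 or macrophage replicate 2 or 3. Dendritic cell markers were higher in 8 of 16 cases and lower in 3 (camera 0.109, and 0.0417 without microglia replicate 1). The higher ones included *Cd209a*, *Ccr7* and *Cd24a* (log2 fold changes 6.69, 3.60 and 3.51). *Cd24a* stood at 18.1, 41.4 and 21.0 CPM in macrophage replicates 1, 2 and 3. *Cd209a* was also highest in replicate 2, as was the neutrophil marker sum, and *Ccr7* in replicate 1. The lower ones were *Itgae* and, chosen after their values were seen, *Fscn1* and *Siglech*. *Itgae* did not pass without microglia replicate 1 (adjusted p = 0.533) or macrophage replicate 3 (0.0594), or with limma-voom (0.183). The counts over the list alone were the same, except 9 dendritic cell markers higher.

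Neutrophil markers were higher in 14 of 15 cases (14 over the list alone), the exception being the receptor gene *Csf3r*, which was chosen after its values were seen and was lower. The median log2 fold change was 8.56, or 6.78 with the 6 genes absent from microglia at their bound. Camera gave an adjusted p of 1.924e-18, and 0.154 with an estimated correlation. *S100a8* stood at 100.5, 242.8 and 128 CPM in macrophage replicates 1, 2 and 3, and *Ltf* at 33.7, 96.1 and 32.9. Without macrophage replicate 2, 14 of the 15 were still called higher. Of 5 choroid plexus and ependymal markers, *Ttr*, *Enpp2* and, chosen after their values were seen, *Kl* and *Clic6* were higher (4 over the list alone, 2 without macrophage replicate 1, and 0 by limma-voom), with an adjusted p of 0.000707 by camera and of 0.363 with an estimated correlation. limma-voom called neither *Ttr* nor *Enpp2* (adjusted p = 0.101 and 0.0621). Their median was 6.54, or 5.41 with the 2 absent from microglia at their bound. *Ttr* stood at 133, 69.6 and 25.3 CPM in macrophage replicates 1, 2 and 3, an order other than that of the neutrophil markers. Whether choroid plexus cells or their RNA were carried along in the sort was not tested.

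**Figure D3:**
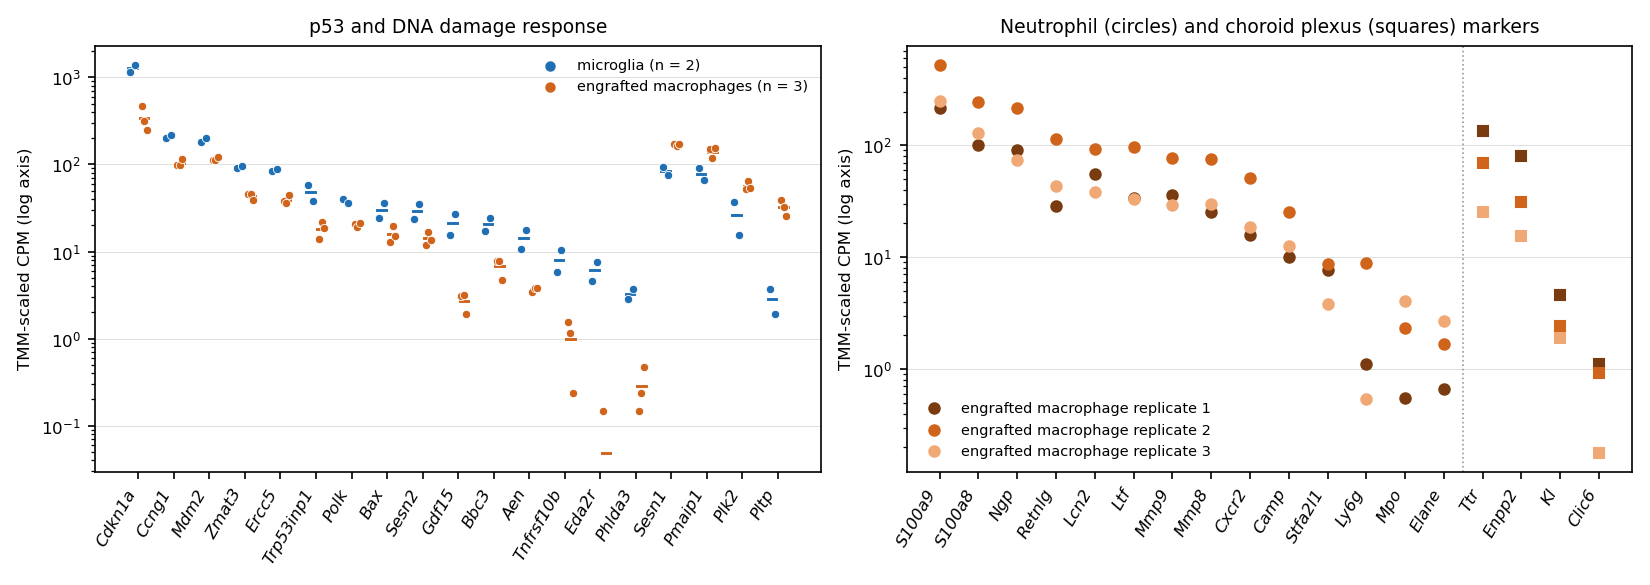
Left, TMM-scaled CPM of the 19 p53 and DNA damage response genes past the threshold, lower in macrophages first, with a point per library and a bar per group mean. Right, CPM per engrafted macrophage library of the 14 neutrophil and 4 choroid plexus markers called higher. Both axes are log axes, on which the 2 macrophage libraries with no *Eda2r* count are not drawn, and *S100a8* and *Ltf* are highest in replicate 2 while *Ttr* is highest in replicate 1.

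Of the 30 lists, 13 passed by camera, 11 higher and 2 lower in macrophages, and 4 of them passed with an estimated correlation (bone marrow-derived brain macrophages, border-associated macrophages, monocytes and type I interferon response). In these 4 lists, 16 of 28, 7 of 22, 5 of 25 and 4 of 39 genes are also in another list. The lists are therefore not independent of each other. With 2 microglia libraries the spread rests on few samples, so a gene that did not pass is not shown to be equal. On simulated counts the edgeR test found 26.2% of genes changed 2-fold. Those runs changed 200 genes each, against 2779 genes called here, so that rate need not hold for these data.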

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

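Leaving out mitochondrial genes or genes shared between lists was chosen after seeing the data, and the rest was planned. No called gene had the opposite sign in any of the 16 settings. The count of called genes was 1014 when tested against a 2-fold change (699 higher, 315 lower), and otherwise 2020 (without macrophage replicate 3) to 3541 (DESeq2), within 1.5 times 2779. Of 2554 results for the 160 named genes, 2455 kept their call, 47 lost it, 52 gained it and 0 reversed. The number of called lists fell from 13 to 4 (4 higher, 0 lower) with an estimated correlation, and fry, which tests a list against no change and not against other genes, called 15 lists higher, engulfment among them (adjusted p = 0.0433), and 4 lower. By camera the engulfment list went from no call to lower without shared genes (adjusted p = 0.0436), and its adjusted p ranged up to 0.969. The causes were not tested, except that a stricter null or fewer genes change the test itself. With the replicate number as a block 2573 genes were called, 84.3% of the 2779 were called again, and the cytokine and dendritic cell lists and *Ptprc* were called (adjusted p = 0.00854, 0.0276 and 0.0164). Macrophage replicate 3 has no microglia partner in that fit and adds nothing to its fold changes. The block fit also leaves fewer residual degrees of freedom than the main fit, so its calls rest on less. The labels name no shared animal, so the numbers are not taken to pair the libraries. Deviations of same-numbered libraries from their group means had correlations of 0.012 and 0.011. With 2 microglia libraries these deviations mirror each other, so they cannot show whether animals were shared. The mean r between groups was 0.851, 0.914 without a filter, 0.813 and 0.875 with prior counts of 0.5 and 5, and 0.838 to 0.865 leaving out each library, and the first component held 51.0% without a filter and 59.3% to 66.5% leaving out each library. Leaving out a microglia library leaves a lone sample assumed to vary like the other group. Depth limits genes near the floor of 3 counts per group.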

Other observations

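Of the tests below, the share of higher genes that follow macrophage replicate 2 was set before its result was seen. The others, and the gene families, were chosen after the results they address had been seen.

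Gene families were formed from symbols sharing the letters before the first digit, with at least 8 tested members. Camera called 10 of 221, 9 higher and 1 lower in engrafted macrophages, and 0 with an estimated correlation, so these are families to look at rather than established shifts. Most genes for ribosomal proteins were higher by small amounts. Of 85 tested, 64 were higher and 0 lower, with median log2 fold changes of 0.78 for the *Rpl* stem and 0.83 for the *Rps* stem, and 0.63 and 0.69 under total count scaling (camera adjusted p = 8.699e-09 and 1.280e-05, and 0.991 for both with an estimated correlation). The *Rps* stem also holds the kinase gene *Rps6ka1*, which was lower. The *Ifi* stem, mostly interferon-inducible genes of the *Ifi200* cluster, was higher for 13 of 16 genes with a median of 3.47 (camera adjusted p = 1.181e-24, and 0.217 with an estimated correlation). Members of this cluster are near-identical, so single genes are uncertain.

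C-type lectin genes (*Clec* stem) were higher for 12 of 21 and lower for 1, *Clec5a*, with a median of 3.67 (camera adjusted p = 8.091e-16, and 0.217 with an estimated correlation). The *Ms4a* genes, membrane proteins of blood cells, were higher for 7 of 10 with a median of 4.45 (2.835e-13, and 0.217). Matrix metalloproteinases (*Mmp*, 7 higher and 1 lower of 13), annexins (*Anxa*, 5 and 1 of 10) and CXC chemokines (*Cxcl*, 6 and 0 of 11) were also higher (0.00525, 0.00754 and 0.00754, and 0.895 for each with an estimated correlation), as were genes with *Cd* names (30 higher and 5 lower of 75, 3.586e-08, and 0.217). The gamma protocadherins of the *Pcdhga* stem, which are adhesion molecules, were lower for 6 of 11 with a median of -1.99 (0.0336, and 0.991 with an estimated correlation), and they share exons, so their counts are uncertain. *Mmp8* and *Mmp9* are also neutrophil markers and were highest in macrophage replicate 2. None of the 10 medians changed sign under the 3 other scalings, but with total count scaling 2 *Cxcl* and 9 *Cd* genes were lower. Genes named in these 2 paragraphs were chosen after their values were seen.

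Neutrophil transcripts varied between the macrophage libraries. The 14 higher markers had a median log2 ratio of 1.21 (SD 0.793) for replicate 2 over the mean of the others, against 0.23 (SD 0.402) for the 19 higher border macrophage markers, a difference of 0.98. Neutrophils or their RNA carried along in the sort, whose gates are not given, and expression by the engrafted macrophages cannot be told apart by these values, because replicate 2 was picked from the same markers. Of the 15 markers, 1 is above 10 CPM in microglia and 1 is also in another list, with *S100a9* at a mean of 329 and *S100a8* at 157 CPM as the most abundant of the higher ones in macrophages. Neutrophils whose share rises with these markers are argued against as the only source of most of the higher genes. Replicate 2 reached 1.5 times both other libraries for 157 of 1545 with enough counts (10.2%, against 4.79% for replicate 1 and 1.49% for replicate 3). A gene with only a part of its counts from neutrophils could stay below that ratio, so a partial share is not addressed. How many of the 14 markers reach the ratio was not counted.

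Microglia genes stood at intermediate levels in engrafted macrophages, which could come from microglia or their free RNA carried into the macrophage sort. If the engrafted cells expressed none of them, a single source would hold all lower homeostatic genes to about the ratio of *Sall1*. Its highest macrophage library was at 5.91% of the microglia mean. The lowest macrophage library lay above that for 25 of the 29 lower homeostatic genes, whose median ratio was 43.8%, so carry-over alone is argued against for those. For *Sall1* itself, *Sall3*, *Slc2a5* and *Upk1b*, which lie below or overlap the *Sall1* range, it stays open. Expression of these genes by the engrafted cells is a biological alternative, which was not tested and remains a hypothesis. These ratios do not tell whether it would be part of a microglia programme.

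Of the 31 tested genes of the p53 and DNA damage response list, 15 were lower in macrophages and 4 higher. Fewer passed without microglia replicate 2, and 2 were higher without macrophage replicate 3. The list did not pass by camera with an estimated correlation (adjusted p = 0.117). Dilution of macrophage RNA by cells that lack the shared genes would lower those genes as much. *Ptprc*, *Csf1r*, *Aif1*, *Spi1* and *Irf8* had a median log2 fold change of -0.017 (SD 0.302), against -0.91 for the p53 list. With *Itgam*, itself lower at -1.15, the median was -0.066 (SD 0.573). Dilution by cells that themselves express the shared genes would not lower them, so these values do not address it. Host microglia were irradiated at transplantation and the donor marrow was given afterwards, so a lasting response to irradiation is a candidate explanation. With 0 libraries from non-irradiated mice, it cannot be told apart from a difference between the cell types that is independent of irradiation.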
